A study of Mus musculus with 12 samples.

How the data were processed

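RNA was sequenced from hearts of 12 wild-type BL6J mice in a chemical model of menopause. The sample labels give left ventricle as the tissue, whereas the series design text names both ventricles, and which holds for the values was not settled. The model uses 4-vinylcyclohexene diepoxide (VCD), a compound that destroys the small ovarian follicles, so that the ovary fails gradually while it stays in place. Per the labels, 4 premenopausal mice received sesame oil, the vehicle, and 4 perimenopausal and 4 menopausal mice received VCD. Stage and treatment therefore change together against premenopause, and only the comparison of menopause with perimenopause is between VCD-treated mice. Per the labels' protocols, RNA was purified from flash-frozen tissue, depleted of ribosomal RNA and made into libraries with a NEBNext Ultra II kit. The labels give no batch, age or cage.

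The authors deposited 1 table of 563 genes with a normalised expression signal for each of 12 libraries, a p-value and 3 log2 fold changes per gene. The unit of the deposited signal is not named; its values are fractional and carry no read counts, so the depth of each library is unknown. Alignment with STAR and the use of DESeq 1.38.0 and R 3.3.3 with the mouse build GRCm38.p6 are named in the submitters' processing notes, with no parameters, and how the signal was scaled is not given in the sources used here. The deposited p-value was recomputed from the values: it is a one-way analysis of variance over the 3 stages on the untransformed signal, with a largest difference from the authors' deposited table of 4.04e-08. The deposited log2 fold changes are log2 ratios of stage means, the later stage over the earlier. The largest p-value in the authors' deposited table is 0.04996, so the table holds only genes already selected on these same libraries at an unadjusted p-value below 0.05. The smallest value of the highest stage mean in the table is 2.02. How many genes were tested before this selection is not given in the sources used here.

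Columns were assigned to stages by their names, which give a stage and a number but no link to a single mouse. No pair of libraries shared a value that would mark a library deposited in duplicate. Gene symbols were matched to the GENCODE annotation of GRCm38, which gave an exon length for 558 of the 563 genes, and coordinates are of that build. Of the genes, 503 are protein coding and 26 are pseudogenes.

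Because the values are not counts, stages were compared with limma 3.58.1 (trend and robust moderation) in R 4.3.3 on log2(value + 1), in genes with a mean of at least 1, a filter that removed none. Fold changes are on that scale, which understates the change of genes with low values. All 12 libraries shared a single estimate of the spread. Every adjusted p is the Benjamini-Hochberg value of limma over the 563 genes, with a threshold of 0.05. Since these genes had been selected on the same libraries, the adjusted p describes order and size within the table and is no independent evidence that a gene changed. The same holds for every other test on these genes that uses the stages. The p-values measure the spread between mice as far as each library is a separate mouse, which the series design states. In 20 simulations of menopause minus premenopause over 563 genes, this fit recovered 54.1% of genes changed 1.5-fold and 84.4% of genes changed 2-fold, with 3.88% false calls, when no selection had taken place. The simulated noise was independent between genes, whereas real libraries could shift many genes together, so these rates may not hold for these data.

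Fixed before the data were examined were 45 gene lists, the tests, the alternatives and the rule for naming genes. In each comparison the rule named the 12 genes with the smallest p in each direction past the threshold, or 5 marked as not past it where fewer than 5 passed. Unnamed gene models and pseudogenes were passed over, and up to 4 members of each list described were added. The oestrogen receptor genes Esr1, Esr2 and Gper1 were on the rule and are not analysed here. Only 48 of the 968 list genes and 23 of the 45 lists were in the table, and 2 lists had the minimum of 5 members. Lists are therefore given as counts. The 2 larger lists were tested with camera (preset correlation of 0.01), with camera using an estimated correlation, and with fry. Lists with at least 2 members, and the sex-linked genes, were described for menopause minus premenopause.

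The alternatives were a pseudocount of 0.1, quantile normalisation, no filter, a mean of at least 5, limma without trend and robust moderation, a fit of only the 2 stages compared, and leaving out each library in turn. Added after seeing the data were a fit without perimenopausal library 3 and menopausal library 4, the 2 libraries with the widest deviations, removal of each library's trend on exon length, array weights, and gene families defined by symbol. Exact permutation tests and random sets were computed with scipy 1.17.1 in Python 3.11.15.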

Results

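The series follows the mouse heart from normal ovarian function through ovarian failure, to find which ventricular transcripts (left ventricle, per the sample labels) differ between premenopause, perimenopause and menopause. There were 4 libraries per stage, and the data were normalised values for 563 genes that the authors had selected. The median value of a library ranged from 7.19 to 8.17 in 11 libraries and was 4.96 in perimenopausal library 3. Values are given as mean ± SD (n = 4 per stage), in the unnamed unit of the table, and log2 changes with their standard error (SE).

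Across the 3 stages, Acta1, Tuba8, Lcn2 and Nes were among the genes that passed the threshold. Skeletal muscle actin Acta1, also expressed in the stressed or immature heart, fell in order of stage from 379 ± 154 to 92.9 ± 21.5 and 53.5 ± 32.1. The tubulin gene Tuba8 was 80.7 ± 9.19, 46.5 ± 7.85 and 36.7 ± 1.82, and Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, was 4.96 ± 2.03, 1.67 ± 0.904 and 0.650 ± 0.172. Nes, the gene of the intermediate filament nestin, was 2.502 ± 0.502, 5.89 ± 1.11 and 7.50 ± 2.36. In limma's F-test over the 3 stages 9 of the 563 genes had an adjusted p under 0.05, and 370 had an unadjusted p under 0.05. Besides those 4 genes they were Rom1, Eps8l1, Tnxb, Erdr1 and the unnamed gene model Gm21887, a list given in full after its values were seen. Without perimenopausal library 3 the F-test called 516 genes, without premenopausal library 1 it called 44, without perimenopausal library 4 it called 19 and without premenopausal library 4 it called 3.

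**Figure D1:**
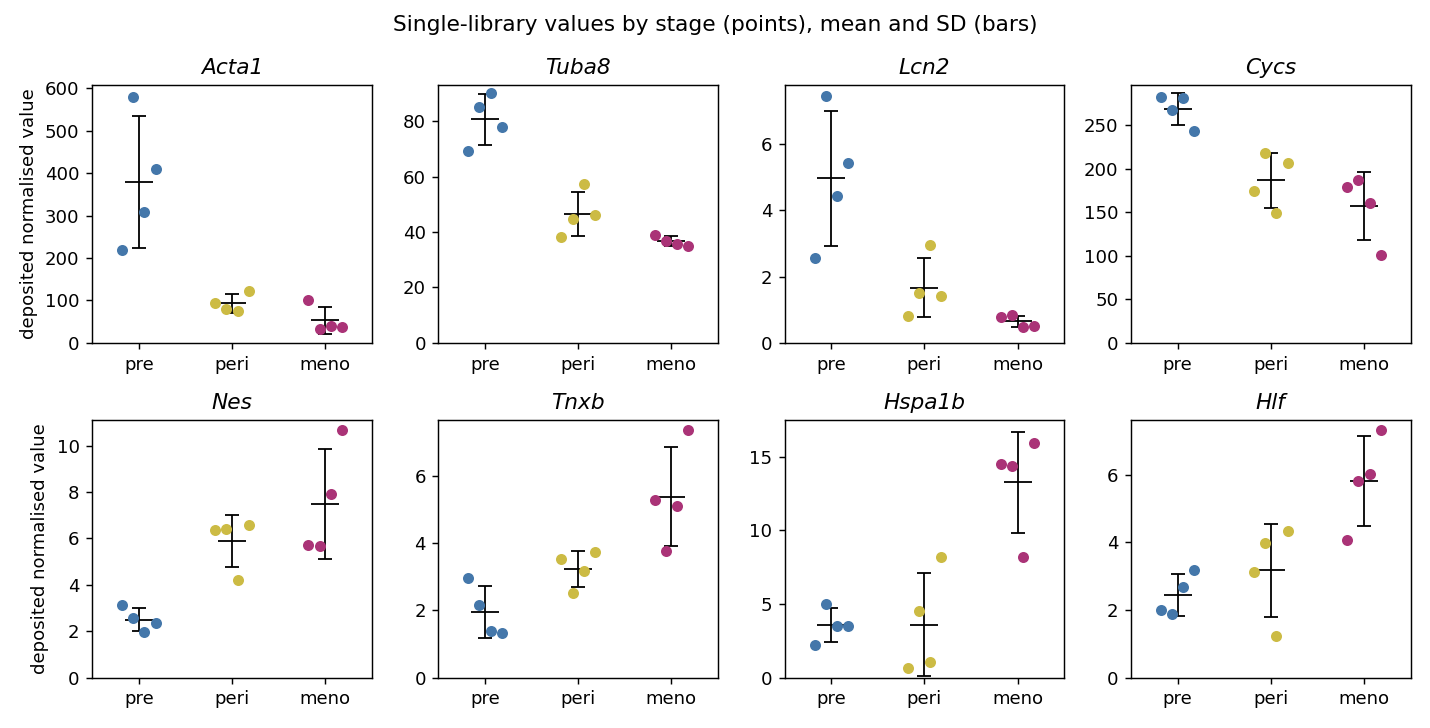
Deposited normalised values (vertical axes, from 0) of 8 genes in the premenopausal (pre), perimenopausal (peri) and menopausal (meno) libraries. Points are single libraries, and bars are the mean and SD of 4. Acta1 averaged 379, 92.9 and 53.5 across the stages, whereas Hspa1b averaged 3.56, 3.61 and 13.3.

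At perimenopause, compared with premenopause, the called genes with names were Erdr1 and Nes, which were higher, and Rom1, Tuba8, Acta1 and Tuba4a, which were lower. Acta1 (chromosome 8, 123891769 to 123894751, minus strand) fell by 1.95 on the log2 scale (SE 0.36, adjusted p = 0.0202). Tuba8 (chromosome 6, 121210696 to 121226854) fell by 0.79 (SE 0.14) and Tuba4a (chromosome 1, 75214228 to 75219865) by 0.71 (SE 0.15). Rom1, known as a photoreceptor disc protein, fell by 0.72 (SE 0.12). Nes (chromosome 3, 87971078 to 87980451) rose by 0.97 (SE 0.20, adjusted p = 0.0315).

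Erdr1 rose by 2.69 (SE 0.46) at perimenopause, and its level in premenopause was 1.57 ± 1.18. It is reported as uncertain, because it correlated at r = 0.939 over the 12 libraries, in log2 values, with Gm21887, a related gene model with which it can share reads. A further 4 named genes did not pass the threshold in the higher or lower direction at an adjusted p of 0.0617: Rasip1 (0.48, SE 0.12), the pacemaker channel gene Hcn2 (0.55, SE 0.14), the carboxylesterase gene Ces1d (1.05, SE 0.28) and the mitochondrial ribosomal protein gene Mrpl19 (-0.56, SE 0.13).

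Of 7 nuclear-encoded oxidative phosphorylation genes none passed the threshold at perimenopause, and none did adjusted over the list alone. Cytochrome c, Cycs, was at 268 ± 18.2 and 187 ± 31.6 (log2 change -0.53, SE 0.20; 0.11 after quantile normalisation), Sdhd at -0.75 (SE 0.34), Uqcrfs1 at -0.54 (SE 0.30) and Ndufa10 at -0.28 (SE 0.17; 0.17 after quantile normalisation). Of 5 heat shock and protein folding genes none passed over the table and 1, Hspb7, did adjusted over the list alone (-0.84, SE 0.25). Hspb6 was at -1.46 (SE 0.62), Hspa1b at -0.29 (SE 0.46) and Dnajb1 at 0.08 (SE 0.27). The adjusted p of camera was 0.536 for oxidative phosphorylation and 0.793 for heat shock, and 0.892 for both with an estimated correlation.

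In all, limma called 7 of 563 genes between perimenopause and premenopause, 3 higher and 4 lower, and 248 had an unadjusted p under 0.05. After quantile normalisation Rom1 (-0.52), Tuba8 (-0.32) and Tuba4a (-0.10) did not pass. The count was 172 without perimenopausal library 3, 24 without premenopausal library 1, 4 without perimenopausal library 2 or menopausal library 3, 3 without premenopausal library 3, and 0 without premenopausal library 2 or 4 or perimenopausal library 1 or 4.

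At menopause, compared with premenopause, named genes that were lower included Acta1, Tuba8, Lcn2 and Ptgds, and named genes that were higher included Nes, Tnxb and Hspa1a. Acta1 fell by 2.86 (SE 0.36, adjusted p = 0.00136), the largest of the named decreases, and Tuba8 by 1.11 (SE 0.14). Lcn2 (chromosome 2, 32384633 to 32388252) fell by 1.79 (SE 0.27, adjusted p = 0.00342), as did the prostaglandin D2 synthase gene Ptgds, from 400.2 ± 107 to 119.8 ± 47.4 (SE 0.35). Nes rose by 1.25 (SE 0.20, adjusted p = 0.00431), and the extracellular matrix gene Tnxb (tenascin XB) by 1.12 (SE 0.21), from 1.95 ± 0.763 to 5.38 ± 1.48.

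Among the other named decreases were enzymes of haem, ketone body and fatty acid metabolism. Alas1, the first enzyme of haem synthesis, was 89.9 ± 9.98 and 39.0 ± 9.50 (-1.21, SE 0.28). The ketone body dehydrogenase gene Bdh1 was 42.5 ± 10.8 and 15.4 ± 5.70 (-1.44, SE 0.34), and Ptpla, now named Hacd1, which acts in very-long-chain fatty acid elongation, was at -0.58 (SE 0.13). Rom1 (-0.84, SE 0.12), Lrg1 (-0.96, SE 0.22), the mitochondrial ribosomal gene Mrpl34 (-1.08, SE 0.25), Cmss1 (-0.73, SE 0.18) and Cnksr1 (-1.05, SE 0.26) also fell.

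The other named increases were Eps8l1 (1.03, SE 0.20), the endothelial GTPase regulator Rasip1 (0.53, SE 0.12), Erdr1 (1.99, SE 0.46, uncertain as above) and Fam212b, now Inka2 (0.76, SE 0.18). Abcc8, which encodes the sulphonylurea receptor of ATP-sensitive potassium channels, rose from 8.30 ± 0.491 to 13.8 ± 2.38 (0.66, SE 0.15). The kinase gene Wnk4 (0.57, SE 0.13), syndecan 4, Sdc4 (0.60, SE 0.14), Ces1d (1.16, SE 0.28), the repressor gene Zbtb7a (0.54, SE 0.14) and the kinase gene Dyrk1b (0.51, SE 0.13) rose as well.

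Of 48 nuclear-encoded oxidative phosphorylation genes on the list 7 were in the table, of which 5 fell at menopause and 2 did not pass (6 fell adjusted over the list alone). None of the 18 tricarboxylic acid cycle genes or 15 mitochondrial genome genes on the lists was in the table. Cycs fell by 0.81 (SE 0.20), Ndufb8 by 0.60 (SE 0.17), Uqcrb by 0.55 (SE 0.21) and Ndufa10 by 0.45 (SE 0.17). After quantile normalisation, which moved the median change of all 563 genes from -0.31 to 0.02, Cycs was at -0.10, Ndufb8 at 0.02, Uqcrb at -0.10 and Ndufa10 at 0.13, and none of the 4 passed. Without menopausal library 4 none of the 7 passed, with Uqcrb at -0.32. The adjusted p of camera was 0.0331, and adjusted p = 0.508 with an estimated correlation. Of 31 fatty acid oxidation genes 2 were in the table: Fabp3, the heart fatty acid binding protein, fell by 0.69 (SE 0.22), and Slc25a20 was at -0.61 (SE 0.41). After quantile normalisation they were at -0.11, no longer past the threshold, and -0.07.

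Both inducible Hsp70 genes rose at menopause, Hspa1a by 1.67 (SE 0.44) and Hspa1b by 1.64 (SE 0.46), together with their cochaperone gene Dnajb1 (0.84, SE 0.27). Hspb7, a small heat shock protein of the heart, fell by 0.67 (SE 0.25), and the fifth member of the list did not pass. These near-identical Hsp70 genes can share reads, so each is uncertain on its own. The adjusted p of camera for this list was 0.198, and adjusted p = 0.508 with an estimated correlation.

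All 3 inflammation genes in the table, of 40 on the list, fell at menopause: Lcn2, the acute-phase gene Serpina3n (-1.36, SE 0.35) and the chemokine gene Ccl9 (-0.67, SE 0.19). All 4 glucocorticoid-responsive genes in the table, of 21 on the list, fell too, and Lcn2 is in both lists. The metallothionein gene Mt2 fell by 2.58 (SE 0.74), the cell cycle inhibitor gene Cdkn1a by 1.30 (SE 0.36) and Sult1a1 by 0.75 (SE 0.20). Mt2 also belongs to the oxidative stress genes, of which 2 of 3 fell, the other being Prdx1 (-0.57, SE 0.21), while Sod2 was at -0.25 (SE 0.19). After quantile normalisation Prdx1 was at -0.07 and did not pass, and Sod2 was at 0.44. Without menopausal library 4 Prdx1 was at -0.35 and did not pass. Only 6 genes of the whole table then passed as lower, Acta1, Tuba8, Rom1 and Lcn2 among them. Most of the other decreases in this paragraph were therefore not called without that library.

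Both circadian clock genes in the table, of 23 on the list, rose at menopause, Hlf by 0.98 (SE 0.26) and Per3 by 0.95 (SE 0.29). Both ion channel genes in the table, also of 23, rose, the potassium channel gene Kcnd2 by 0.88 (SE 0.28) and Hcn2 by 0.41 (SE 0.14). Of 4 sarcomere genes, Cryab (-0.72, SE 0.24) and Csrp3 (-0.55, SE 0.20; 0.00896 after quantile normalisation) fell, and Myom2 (1.17, SE 0.49) and cardiac actin Actc1 (-0.80, SE 0.36; 0 after quantile normalisation) did not pass. In the fetal and hypertrophic programme Acta1 fell and Fhl1 was at -0.87 (SE 0.51). None of the 3 calcium handling genes passed, with Casq1 at -1.05 (SE 0.42), Casq2 at -0.54 (SE 0.50) and Slc8a1 at -0.25 (SE 0.50; 0.40 after quantile normalisation).

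Of 3 lipid storage and sterol genes the lipid droplet gene Plin5 fell by 0.85 (SE 0.21), and Srebf1 (-0.39, SE 0.42) and Plin2 (-0.21, SE 0.20) did not pass. Of 2 protein breakdown genes Map1lc3a fell by 0.51 (SE 0.16; 0.15 after quantile normalisation) and Fbxo32 was at 0.59 (SE 0.44). Neither of 2 glycolysis genes passed, Pgam1 at -0.50 (SE 0.29) and Gapdh at -0.32 (SE 0.27), and both correlated with a pseudogene of their own over the 12 libraries (r = 0.970 and 0.998). Neither of 2 smooth muscle and pericyte markers passed, Notch3 at 0.86 (SE 0.36) and Mylk at 0.47 (SE 0.25). Of the 8 genes on the sex-linked list, Xist was the 1 in the table, and it rose by 1.52 (SE 0.41), from 2.51 ± 3.16 to 7.01 ± 1.26. In premenopausal library 1 it was at 7.25, as high as at menopause, against 0.860 to 1.06 in the other premenopausal libraries.

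In all, limma called 290 of 563 genes between menopause and premenopause, 110 higher and 180 lower, and 376 had an unadjusted p under 0.05. The adjusted p of many genes lay just under the threshold, and the count was 6 without premenopausal library 2, 5 without premenopausal library 3 or 4 or menopausal library 3, 12 without menopausal library 4 and 524 without perimenopausal library 3. After quantile normalisation 176 genes were called, 86 higher and 90 lower. Of the genes named above as called, those that then did not pass also included Mrpl34 (-0.54), Cmss1 (-0.27), Ptpla (-0.24), Cryab (-0.24), Plin5 (-0.23), Hspb7 (-0.15), Sult1a1 (-0.51), Hcn2 (0.21), Wnk4 (0.29), Sdc4 (0.43) and Zbtb7a (0.39). Changes followed exon length across genes (Spearman rho of 0.536 across 558 genes, which are not independent replicates), and 147 genes were called with each library's length trend removed.

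Between menopause and perimenopause, the only contrast within VCD-treated mice, no gene passed the threshold, and the smallest p belonged to the inducible heat shock gene Hspa1b. Hspa1b was 3.61 ± 3.52 at perimenopause and 13.3 ± 3.43 at menopause (log2 change 1.94, SE 0.46), and Hspa1a was 4.83 ± 3.95 and 13.7 ± 3.85 (1.57, SE 0.44). Eps8l1 (0.71, SE 0.20) and the transcription factor genes Etv5 (0.76, SE 0.21) and Zfp366 (1.06, SE 0.32) had the next smallest p in the higher direction. In the lower direction stood Ccdc58 (-0.54, SE 0.17), Cenpv (-0.65, SE 0.21), Mrpl36 (-0.72, SE 0.24), Ptgds (-1.04, SE 0.35) and Bud31 (-0.40, SE 0.15). All 10 had an adjusted p of 0.165.

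Of the 5 heat shock genes, 3 passed adjusted over the list alone (Hspa1a, Hspa1b and Dnajb1, at 0.76, SE 0.27), and Hspb6 was at 0.63 (SE 0.62). Of the 7 oxidative phosphorylation genes none passed, with Ndufb8 at -0.42 (SE 0.17), Uqcrb at -0.36 (SE 0.21), Cycs at -0.27 (SE 0.20) and Atp5c1 at -0.18 (SE 0.13). The adjusted p of camera was 0.0180 for heat shock, upward, and 0.0141 for oxidative phosphorylation, downward, and adjusted p = 0.249 for both with an estimated correlation. The limma count was 0 of 563 genes, with 151 at an unadjusted p under 0.05. It was 1 without perimenopausal library 4.

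All 7 genes called at perimenopause were also called at menopause in the same direction, 3 higher and 4 lower. Independent lists would share 0.586 higher and 1.28 lower genes. In simulations all 12 libraries were drawn around each gene's overall mean. Both later stages were compared with the same simulated premenopausal group and shared 0 genes. With no stage effect and noise independent between genes, hardly any gene could be called, so that count says little. Over the 563 genes the 2 log2 changes correlated at r = 0.731, against 0.496 simulated, with a covariance of 0.232 against 0.0350. These are across genes, which are not independent replicates. The simulated groups had no selection, while the 563 genes were selected on the same stages, so the excess over the simulated values cannot be read as a shared effect. With the premenopausal libraries split 2 and 2 in 6 ways, 0 to 1 genes were shared, r was 0.569 to 0.754 and the covariance 0.191 to 0.241. The shared count was 156 without perimenopausal library 3 and 22 without premenopausal library 1. It was 3 without menopausal library 3, 2 without perimenopausal library 2, 1 without premenopausal library 3, and 0 without premenopausal library 2 or 4 or perimenopausal library 1 or 4.

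**Figure D2:**
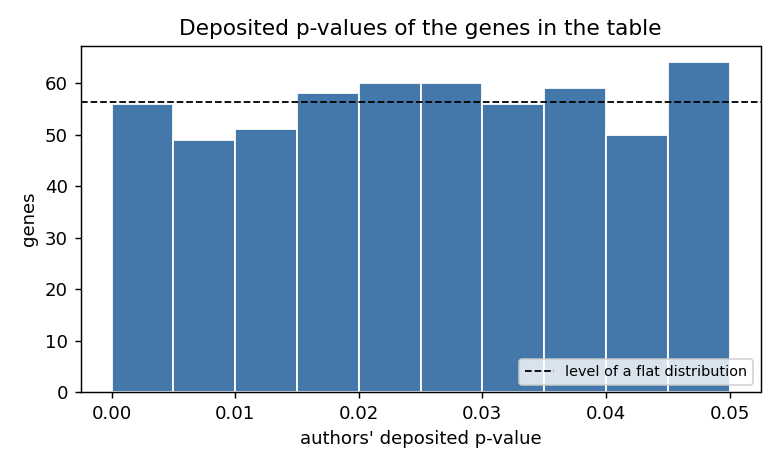
Number of genes (vertical axis) in 10 equal intervals of the p-values in the authors' deposited table (horizontal axis). The dashed line is the level of a flat distribution. The 10 bars hold 49 to 64 genes each, and 274 of the 563 genes lie under 0.025.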

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

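The tests of the deposited p-values and of perimenopausal library 3 were chosen after the result was seen, as were the alternatives that left out both wide libraries or used array weights. In 22 of 237 groups of 4 values, 1 library stood apart from the other 3 by more than a published limit for such gaps, where chance gives about 11.9 (1 in 20). Perimenopausal library 3 held 12 of the 22.

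In perimenopausal library 3, Erdr1 was at 25.9 (10.1 to 12.6 in the other perimenopausal libraries), Nes at 4.22 (6.35 to 6.56) and Alas1 at 19.8 (48.5 to 49.7). Kcnd2 was at 0.915 (3.43 to 3.85), Slc25a20 at 16.1 (73.5 to 82.4), Pgam1 at 9.71 (26.6 to 28.2) and Hspb7 at 199 (449 to 498). Fbxo32 was at 1.65 (11.5 to 12.6), Myom2 at 28.0 (140 to 153), Xist at 2.23 (4.21 to 4.61), Notch3 at 0.384 (3.47 to 4.07) and Mylk at 0.180 (1.66 to 1.93).

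In the other libraries, Xist was at 7.25 in premenopausal library 1 against 0.860 to 1.06 in the other premenopausal libraries. The same library had Mt2 at 14.4 (100.1 to 117) and Sdc4 at 4.77 (3.55 to 3.72). Sult1a1 was at 30.3 in premenopausal library 2 (17.9 to 19.8) and Uqcrb at 528 in premenopausal library 3 (453 to 465). Menopausal library 1 had Rom1 at 5.63 (4.06 to 4.27), Acta1 at 101.4 (33.4 to 40.8) and Srebf1 at 9.50 (6.33 to 6.82). Menopausal library 4 had Atp5c1 at 533 (673 to 689) and Kcnd2 at 6.94 (3.46 to 3.86).

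Perimenopausal library 3 lay lower than the mean of the other perimenopausal libraries in 440 of the 563 table genes. Its deviation fell with exon length (Spearman rho of -0.319 across 548 genes of at least 200 bases), with a median of -0.27 in the 137 shortest genes and -1.07 in the 137 longest, so a loss of long transcripts may account for part of it. A very shallow or failed library stays open: 12 genes in it shared 1 low level (value times exon length within 5% of 1 number). All of them were small RNAs, pseudogenes or unnamed models. That level was 11.3, with 1 gene below it. In another library up to 5 genes lay that close together. The levels in the other libraries were 500 to 2077, with 3 to 19 genes below. Med12, a widely expressed gene outside those 12, was at 0.00123 in perimenopausal library 3 and at least 2.78 in the other perimenopausal libraries. No biological explanation was tested, since the labels single out no perimenopausal mouse. Without this library limma called 524 genes in place of 290 at menopause against premenopause.

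The p-values in the authors' deposited table were flat: 48.7% lay under 0.025, inside the interval of 45.8% to 54.2% that a flat distribution of 563 values gives. Such a distribution is what selection by chance among unaffected genes would leave, so part or all of the selection may be chance. If 11260 genes had been tested, 563 would be 5% of them, and a Benjamini-Hochberg threshold of 0.05 would pass any gene only with at most 3984 tests. Wide libraries that hid stronger differences stay open too. Without perimenopausal library 3 and menopausal library 4 the median p of the analysis of variance was 0.0164, and the lowest of the 15 other pairs gave 0.0153, which the bound set beforehand counted against this explanation. The 95% interval of the difference over 2000 resamplings of genes, a test added after the result was seen, was -0.00151 to 0.00344 and includes 0. Genes are not independent replicates and the libraries stayed fixed, so this interval does not measure the spread between libraries and decides nothing. The pairs with perimenopausal library 3 left out gave at most 0.0261 and the other 12 pairs at least 0.0307. The F-test called 475 genes without both wide libraries in place of 9. It called 516 without perimenopausal library 3 alone and 9 without menopausal library 4 alone, so the rise went with perimenopausal library 3. A real difference between stages remains open.

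Other splits of the libraries into the same group sizes were counted. At menopause against premenopause 1 of 35 splits, the real one, gave as many as 290 genes, and the highest of the others gave 0. In the F-test 2 of 100 splits gave as many as 9 genes, and the highest other gave 43. Neither share excludes chance, because the genes had been selected under the real split, which favours it. At perimenopause against premenopause 2 of 35 splits gave as many as 7 genes (highest other 19), so chance was not excluded there despite that advantage. At menopause against perimenopause the real count was 0, which all 35 splits reach whatever the values (highest other 1), so the count says nothing about chance.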

How the results depend on the processing

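The fits without both wide libraries, with the length trend removed and with array weights were chosen after seeing the data. The counts-only alternatives (DESeq2 and its size factors) were not run, because the deposited values are not counts. No paired analysis was possible because the columns carry only a number within each stage, with no link to a shared litter, day or mouse. Counts of genes depended strongly on the processing. Of 97 named results, 82 kept their sign under every alternative run, and 1603 of 2018 values kept both sign and side of the threshold. These shares say little about robustness, since the results were named for their small p in a selected table. Several alternatives also leave each log2 change as it is: no filter, limma without trend and robust moderation, and a fit of only the 2 stages compared. So does leaving out a library of the stage outside a comparison. Among the named results called at menopause against premenopause, only Acta1, Tuba8, Rom1, Lcn2 and Nes stayed past the threshold in every alternative run. Their highest adjusted p in limma was 0.0101, 0.0436, 0.0186, 0.0201 and 0.0243. Removing the filter changed no count, and limma without trend and robust moderation or with a mean of at least 5 kept each total count of genes within 1.5 times. The latter filter left 357 genes. At menopause against premenopause it gave 51 higher and 154 lower, in place of 110 and 180.

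With a pseudocount of 0.1 the F-test over the stages called 5 genes. Quantile normalisation gave 125 genes in the F-test, 42 at perimenopause (21 higher and 21 lower), 176 at menopause (86 and 90), 1 between the later stages and 33 shared. A fit of only the 2 stages compared gave 4 genes at perimenopause and 514 at menopause (217 and 297). Without both wide libraries these were 475, 319 (110 higher and 209 lower), 515, 1 and 296. With the length trend removed they were 67 in the F-test, 43 and 147 against premenopause, and 36 shared. Array weights gave 550, 415, 539, 1 and 400. Of the 290 genes called at menopause, 124 were called in the same direction after quantile normalisation, 124 with the length trend removed, and 289 without both wide libraries. The cause was not tested. Leaving out 1 library at a time gave 3 to 516 genes in the F-test, 0 to 172 at perimenopause, 5 to 524 at menopause, 0 to 1 between the later stages and 0 to 156 shared.

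Of the 2 gene lists tested by camera, 0 passed at menopause against premenopause in place of 1 after quantile normalisation, without both wide libraries, with the length trend removed or with an estimated correlation, and 0 to 1 when 1 library was left out. Between the later stages 1 passed in place of 2 after quantile normalisation or without both wide libraries, 0 with an estimated correlation or with fry, and 1 to 2 when 1 library was left out.

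After quantile normalisation, the sign turned at menopause against premenopause for Slc8a1 (0.40), Pgam1 (0.0159), Gapdh (0.11), Plin2 (0.0787), Ndufb8 (0.0151), Ndufa10 (0.13), Sod2 (0.44), Map1lc3a (0.15) and Csrp3 (0.00896), and at perimenopause for Cycs (0.11) and Ndufa10 (0.17), and Actc1 at menopause against premenopause was at 0. This setting moved the median of all genes by itself, and the cause of single changes was not tested. Between the later stages Hspb6 was at -0.0709 without both wide libraries, at -0.16 with array weights and at -0.22 to 0.96 with 1 library left out. At perimenopause Hspa1b was at 0.31 with array weights and at -0.74 to 0.0800 with 1 library left out, and Dnajb1 was at -0.16 to 0.27. Depth is unknown, so what it limits could not be assessed.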

Other observations

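The families defined by gene symbol and their tests were chosen after the values were seen, as was the fit that decided on exon length, and the tests on menopausal library 4 and on the premenopausal level were set before their results. The table held 29 mitochondrial ribosomal protein genes, which build the ribosome that translates the mitochondrial genome, and all 29 were lower at menopause than at premenopause. Of them 22 fell in limma and 7 did not pass, with changes from -1.08 (Mrpl34) to -0.38 and a median of -0.56. Of the other 534 table genes, 54.9% were lower. All 22 genes of respiratory chain subunits and assembly factors were lower too, and 15 fell, among them Cox19 at -0.79, Ndufb4 at -0.80 and Coa3 at -0.64. With each library's length trend removed 6 of the 22 fell, at a median of -0.45 in place of -0.55. In the main fit, which gave the -0.55, length-matched sets of other table genes had a median of -0.43. Those sets could hold ribosomal protein genes. All 8 import and carrier genes were lower, of which Tomm5 (-0.95), Slc25a3 (-0.61) and the ADP/ATP carrier gene Slc25a4 (-0.50) fell. The 3 tubulin genes fell, at a median of -0.84. No test of these families against the other genes is given, because they were picked from their values in a table selected on the same stages. With both wide libraries left out, all 29 and all 22 genes passed, at medians of -0.43 and -0.41. After quantile normalisation, 5 and 3 fell, at medians of -0.29 and -0.12, as did 1 of the import and carrier genes (median -0.10 in place of -0.57) and 1 tubulin gene (median -0.23). Without menopausal library 4, 0 of the 22 respiratory genes passed, at a median of -0.41, 0 of the 8 import and carrier genes (-0.42) and 1 of the 3 tubulin genes (-0.78). Such a loss was not particular to that library. Without premenopausal library 2, 3 or 4 or menopausal library 3, only 4 genes of the whole table passed as lower.

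At perimenopause 28 of the 29 ribosomal genes and all 22 respiratory genes were lower than at premenopause, with medians of -0.44 and -0.41, and none passed the threshold singly. Of the other table genes 69.5% and 69.7% were lower. The medians were -0.07 and -0.02 after quantile normalisation, and length-matched sets of other table genes had medians of -0.29 and -0.33. Each of those sets could hold genes of the other families. The mean of log2(value + 1) over the ribosomal genes was 4.80 ± 0.107 at premenopause, 4.36 ± 0.234 at perimenopause and 4.21 ± 0.315 at menopause (n = 4). In each of the 4 perimenopausal and 4 menopausal libraries it lay below all 4 premenopausal ones. No p-value is given for these means either.

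Several technical explanations for the lower ribosomal protein genes at menopause were weighed. Changes followed exon length across the table (Spearman rho of 0.536 across 558 genes), from a median of -0.55 in the 141 shortest genes to 0.56 in the 140 longest. A comparison with length-matched sets of other table genes (median -0.38) had been planned, and its p is left out because the family was picked from its values. A linear length trend alone did not account for these values, judged by a bound written after they were seen. With each library's trend removed, the median of the shortest genes moved to -0.26. That of the ribosomal genes was -0.53 (median SE 0.20) in place of -0.56 (median SE 0.20), with all 29 lower. Of them 12 passed in place of 22, while 21 had an unadjusted p under 0.05 in place of 23, because the adjusted p rose as fewer table genes differed. Length as part of the source, or through a trend that is not linear, stays open. The length-matched sets were lower too, and the shortest genes kept a median of -0.26. Neither set excluded the other mitochondrial families, and the shortest genes did not exclude the ribosomal genes. These medians therefore do not separate length from the families. A premenopausal level set by libraries 2 to 4 stays open too: against premenopausal library 1 the median was -0.49, but 1 library has no spread, so the bound set beforehand decides nothing.

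The other menopausal libraries argue against menopausal library 4 as the only source. The mean of log2(value + 1) over the ribosomal genes was 4.38, 4.46 and 4.24 in menopausal libraries 1 to 3. It was 4.69 to 4.92 in the premenopausal libraries. How much of the fall came from menopausal library 4 stays open. Without that library the median was -0.43 (median SE 0.17) in place of -0.56 (median SE 0.20), and all 29 genes were lower. Only 1 of 29 then passed the threshold, so the bound set beforehand, which asked for most genes to stay called, was not met in that fit, although 19 had an unadjusted p under 0.05. With perimenopausal library 3 left out as well, the median was the same, its median SE was 0.11 and all 29 passed. That fit was chosen after the planned one had been seen, and it changed only the spread. The genes had also been selected with menopausal library 4 included, so that fit decides nothing. An effect of ovarian failure or of VCD itself remains possible and could not be separated by this design.

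For each library, the log2 deviation from the gene mean over the 12 libraries was fitted on log2 exon length. These relative slopes were -0.0813 ± 0.0457 per doubling at premenopause, -0.0194 ± 0.0518 at perimenopause and 0.101 ± 0.0874 at menopause (n = 4). The 4 menopausal slopes (0.0342 to 0.225) lay above the 4 premenopausal ones (-0.117 to -0.0170). The exact permutation p of that comparison, 0.0286, is the smallest that 4 libraries against 4 can give, and over 3 comparisons it became 0.0857, so it does not show that slopes were alike. Menopausal library 4 had the steepest slope, 0.225.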
